A study of Mus musculus with 2 samples.

How the data were processed

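MicroRNA sequencing was carried out on total RNA from the left cerebral cortex of adult female mice of the 5xFAD/CAST strain, aged 8 to 10 months. 5xFAD is a transgenic mouse model in which amyloid plaques form in the brain. The labels give RNA fragments under 30 nt as the size range of the libraries. The 2 libraries carry biological replicate numbers 1 and 2 and form 1 group. Both libraries name the same donor entry and different tissue samples, and nothing in the labels says that the tissue came from separate animals. P-values therefore concern only the difference between these 2 libraries, which may be technical. The binomial test described below sets that difference against counting error and holds no estimate of the spread between replicates.

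Each library has a table of raw read counts per miRNA gene that the authors deposited, with 1 row per gene of GENCODE release M21 on mm10, per the record accompanying each file. The tables hold counts on either strand, on the strand of the gene and on the opposite strand, as worked out from the column totals and the annotation. Replicates were not pooled. The aligner, the counter, adapter trimming and their versions are not given in the sources used here. The counts were not normalized by the authors. The first 4 rows of each table name no gene and hold reads that were unmapped, mapped to several places, lay outside the miRNA genes or were ambiguous. These rows made up 67.4% of the reads in replicate 1 and 67.6% in replicate 2 and stayed out of library sizes and tests. Reads that map to several places are in a row of their own, so hairpins with near-identical mature sequences at several loci can lose counts. A row is a hairpin gene, so the 5p and 3p mature arms were summed. Reads from a strain that differs from the reference sequence could map less well, and this was not analysed here. Signal tracks were not used here.

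The IDs of the tables matched the M21 miRNA genes in full (2202 genes), and symbols, coordinates and hairpin sequences were taken from that annotation. Each hairpin was called intronic, exonic, UTR, coding or intergenic from the genes on its own strand, with a protein-coding host taken first. Counts on the strand of the gene were the main measure, as set before the data were examined. CPM values (counts scaled to a common total) were computed over all counts on miRNA genes. Values are means ± SD over the 2 libraries. Means and SDs of 2 values are imprecise. A gene was called detected at 10 CPM or more in both libraries.

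The only comparison the design allows is replicate 2 against replicate 1, which compares those libraries, not conditions. Each gene with at least 10 counts in the sum was tested with a two-sided exact binomial test against the share given by TMM-scaled library sizes, with Benjamini-Hochberg adjustment and a threshold of 0.05. Ratios of the libraries are TMM-scaled with 0.5 counts added to each library. The biological coefficient of variation (BCV) is the square root of the common dispersion of an intercept-only edgeR fit, with 1 residual degree of freedom per gene. For 20 gene lists of cell types, organs, clusters and families, all written before the data were examined, the share of counts and the median log2 ratio were computed. Lists with at least 3 tested members were placed among 10000 random lists of the same size matched on mean expression. That percentile describes these libraries and is not a p-value. The lists were neuron, astrocyte, oligodendrocyte, microglia and immune, endothelium and mural, meninges and fibroblast, blood, choroid plexus and ependyma, epithelium, muscle and heart, liver, gut and pancreas, posterior Hox clusters, embryonic stem, activity-regulated, Alzheimer literature, let-7, miR-30, miR-181, miR-17~92 with its paralogs, and the Dlk1-Dio3 cluster.

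Named genes were the 25 with the highest mean CPM, the 3 most abundant members of each list, all members of the blood and Alzheimer literature lists, the 5 largest ratios in each direction among called genes with at least 100 counts in the sum, and the 5 with the most opposite-strand counts. Other genes named in the text were chosen after their values were seen. Alternatives were the unstranded column, DESeq2 size factors or total counts for scaling, other filters on low counts, other denominators, another pseudocount, Spearman's coefficient, an edgeR exact test with a fixed BCV of 0.1, and leaving out each library.

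The methods were tested on simulated data for replicate 2 against replicate 1, with 546 genes. Of 200 genes changed by 2-fold, 68% were recovered, and 2.02% of unchanged genes were called. The binomial test allows for counting error alone. The 2.02% is therefore not an error rate for libraries that also vary otherwise, as these 2 did (BCV 0.481). Simulated BCVs of 0.1, 0.3 and 0.5 were estimated as 0.09855, 0.299 and 0.497. Of 200 random lists, 5% lay outside the central 95%. Such lists hold members drawn at random, so this share does not cover lists whose members belong to 1 cluster or family. Binomial intervals are Wilson 95% intervals unless named as exact. The reads carry no molecular identifiers in the tables used here, so intervals and floors cover counting error only. A count of 0 allows up to 3 counts, which is 0.710 CPM in replicate 1 and 0.581 CPM in replicate 2. Software versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.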

Results

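MicroRNA genes were profiled in the left cerebral cortex of 5xFAD/CAST female mice in 2 libraries of 1 group. The labels state no second genotype, age or treatment, so levels are described within the tissue and the 2 libraries are compared with each other. The tables held 12978140 reads for replicate 1 and 15950006 for replicate 2. Of these, 4226300 and 5162369 were counted on the strand of a miRNA gene, a share of 32.5% ± 0.14 (SD, n = 2). Reads mapping to several places took 39.9% ± 0.689. Of 2202 annotated miRNA genes, 309 reached 10 CPM in both libraries and 1427 had no count in either.

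Among the counted reads, which leave out those mapping to several places, the let-7 family, Mir139, Mir744, Mir127 and Mir132 were prominent. Mirlet7g (ENSMUSG00000065440.1), a member of the let-7 family that restrains proliferation and marks differentiated cells, stood at 118079 CPM ± 24708 (SD, n = 2). It lies on chromosome 9 from 106178840 to 106178927 in an intron of Wdr82. Mir139 (ENSMUSG00000065446.1; chromosome 7, 101475376 to 101475443, in an intron of Gm45837) stood at 117333 ± 37043 CPM, so the order of these 2 genes was within the spread between libraries. Mir132 (ENSMUSG00000065537.2; chromosome 11, 75173682 to 75173747, in an intron of 1700016P03Rik), which is induced by neuronal activity and promotes dendrite growth, stood at 30883 ± 13710 CPM. The 10 most abundant genes took 57.3% ± 0.305 of the counts and the 25 most abundant took 74.0% ± 1.16.

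**Figure D1:**
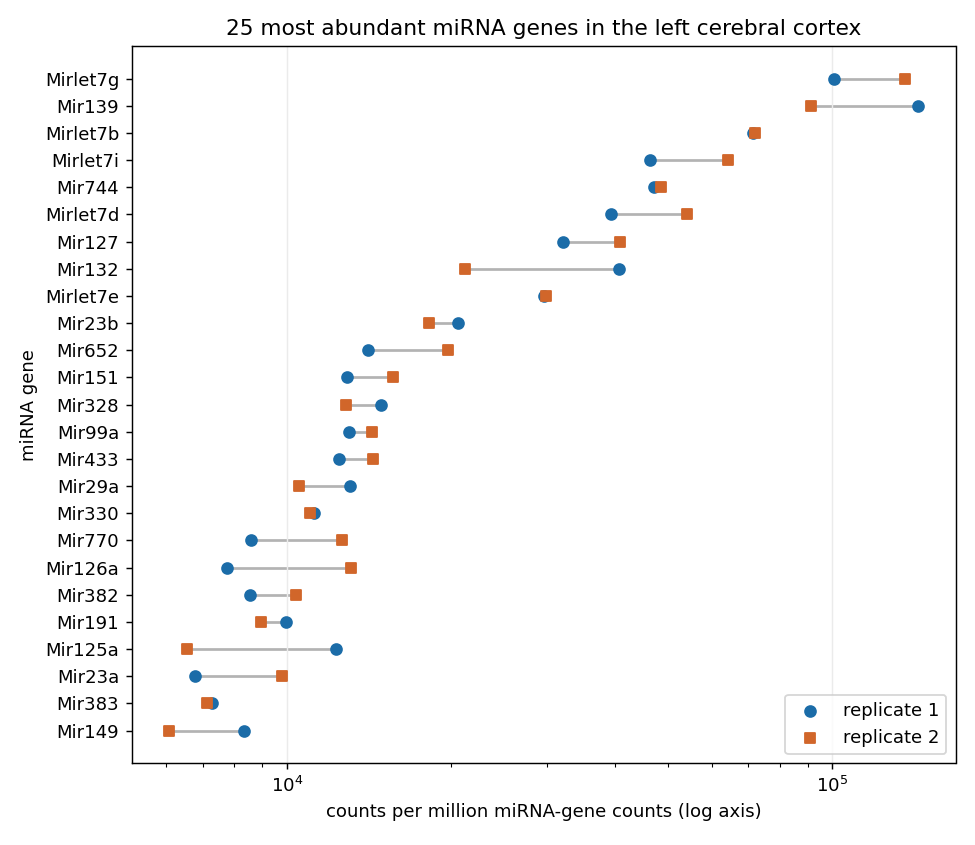
CPM (log axis) of the 25 most abundant miRNA genes in replicate 1 (circles) and replicate 2 (squares), with a line joining both libraries. Mir139 led replicate 1 at 143526 CPM and Mirlet7g led replicate 2 at 135551 CPM.

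All 12 members of the let-7 list were detected, and together they took 33.2% ± 4.99 of the counts. Mirlet7b had 71717 CPM ± 374, Mirlet7i 55297 ± 12630, Mirlet7d 46634 ± 10409 and Mirlet7e 29708 ± 224 (SD, n = 2 each). Mirlet7a-1, Mirlet7c-2 and Mirlet7f-1 share stretches of 18 bases with other loci on both sides of the hairpin centre, so their counts are uncertain. Hairpins that share such a stretch on 1 side, as Mirlet7g, Mirlet7b and Mirlet7i do, can lose reads of that side too. The miR-30 list took 1.45% ± 0.0867, led by Mir30d, and the miR-181 list took 0.416% ± 0.0296. The miR-17~92 cluster with its paralogs, which promotes proliferation, took 0.277% ± 0.0104.

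MiRNA genes of the imprinted Dlk1-Dio3 cluster on chromosome 12, expressed from the maternal allele and abundant in brain, took 11.4% ± 1.13 of the counts. Of 55 members, 47 were detected and 7 were among the 50 most abundant genes. Mir127, which is antisense to the imprinted gene Rtl1, had 36360 CPM ± 6189, Mir433 had 13418 ± 1374 and Mir770, in an exon of Meg3, had 10580 ± 2843 (SD, n = 2 each).

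The neuron list took 10.8% ± 1.29 of the counts with 22 of 26 members detected. Mir127 is also on this list, and apart from Mir127 and Mir132 its most abundant member was Mir383 at 7217 CPM ± 110. Mir137, linked to neuronal maturation, had 5889 ± 169 CPM, and Mir138-1, which limits dendritic spine size, had 4532 ± 408. Mir138-1 shares an 18-base stretch with Mir138-2 on 1 side, so its counts are uncertain. The activity-regulated list took 4.65% ± 1.32, and the Alzheimer literature list took 5.21% ± 1.42. Mir132 is on both lists. Further members of the Alzheimer literature list were Mir29a, which targets Bace1, at 11770 ± 1779 CPM, Mir107 at 3124 ± 1355 and Mir34a at 3094 ± 246 (SD, n = 2 each). Mir107 shares 18-base stretches with the Mir103 loci on both sides, so its counts are uncertain. With 1 group, none of these levels can be set against mice without the transgenes.

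The Mir124a and Mir9 families, each encoded at 3 loci, had few counts. The 3 Mir124a genes, whose product is a main miRNA of neurons, had 17 counts in replicate 1 and 28 in replicate 2, or 4.72 CPM ± 0.991 together. The 3 Mir9 genes, whose product acts in neural progenitors and astrocytes, had 110 ± 2.4 CPM together. Each of these 6 hairpins shares 18-base stretches with another locus on both sides, and reads mapping to several places are outside these counts. The counts of Mir124a and Mir9 are therefore uncertain.

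The lists of glial and vascular miRNA genes took lower shares than the neuron list. Shares are sums over lists of unlike size, so they do not rank cell types. The neuron list has 26 members, astrocyte 12, oligodendrocyte 5, microglia and immune 8 and endothelium and mural 5. The astrocyte list took 4.35% ± 0.283, led by Mir23b at 19398 CPM ± 1713. The hairpins of Mir23b and Mir23a, both on this list, share a stretch of bases with each other on 1 side. Their counts and the astrocyte share are therefore uncertain. The oligodendrocyte list took 0.622% ± 0.124, nearly all from Mir219a-2 at 3287 ± 267 CPM and Mir338 at 2923 ± 979, both of which promote oligodendrocyte differentiation. Both genes lie opposite another miRNA gene and had 0 counts in the unstranded column, where the share was 0%. Mir219a-2 also shares a stretch of bases with Mir219a-1 and Mir219c on 1 side, and reads mapping to several places are outside these counts. The counts of Mir219a-2 and the oligodendrocyte share are therefore uncertain. The microglia and immune list took 0.449% ± 0.219, led on average by Mir21a at 2128 ± 1738 CPM, with Mir155, a miRNA of inflammatory activation, at 177 ± 5.49. In replicate 2, Mir146 was higher than Mir21a (1074 against 899 CPM). Mir146 shares a stretch of bases with Mir146b on 1 side, so its counts are uncertain too. The share of the microglia and immune list was 0.604% in replicate 1 and 0.294% in replicate 2. The endothelium and mural list took 1.63% ± 0.428, led by the endothelial Mir126a at 10439 ± 3794 CPM and the smooth-muscle Mir143 at 5656 ± 537 (SD, n = 2 each). With the unstranded column that share was 0.629%, as Mir126a kept 2 counts per library there.

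Lists of other tissues took little of the counts. The choroid plexus and ependyma list took 0.134% ± 0.0503, the blood list 0.0490% ± 0.0566 and the liver, gut and pancreas list 0.0488% ± 0.0130. The blood share was 0.00897% in replicate 1 and 0.0890% in replicate 2, and its mean was 0.00247% with the unstranded column. The epithelium list of the miR-200 family took 0.0369% ± 0.0219, the posterior Hox list 0.0147% ± 0.0034, the muscle and heart list 0.00625% ± 0.0000232 and the meninges and fibroblast list 0.00337% ± 0.000686. The epithelium share was 0.0523% in replicate 1 and 0.0214% in replicate 2. The embryonic stem list averaged 0.0212% ± 0.0299, from 0.0424% in replicate 1 and 0.0000581% in replicate 2. By position, intronic hairpins held 52.9% ± 1.97 of the counts, exonic ones outside coding and UTR sequence 28.6% ± 1.90 and intergenic ones 17.04% ± 0.335.

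Between the libraries, the Mir302 cluster, known for its high expression in pluripotent cells, was counted almost entirely in replicate 1. Its hairpins Mir302a to Mir302d had 1786 counts in replicate 1 and 1 count in replicate 2, a CPM ratio of 2182 with an exact 95% interval of 391 to 86220. Mir302a (ENSMUSG00000065552.1; chromosome 3, 127545496 to 127545564, intergenic) was at least 273-fold higher in replicate 1, against a floor of 3 counts in replicate 2. Mir26a-2, in a UTR of Ctdsp2, was 37.2-fold higher in replicate 1. Its hairpin shares a stretch of bases with Mir26a-1 on 1 side, and reads mapping to several places are outside these counts. The counts of Mir26a-2 and their ratio are therefore uncertain. In the other direction, Mir451a, an erythroid miRNA (ENSMUSG00000070065.1; chromosome 11, 78073170 to 78073241, intergenic), was 26.7-fold higher in replicate 2, from 127 and 4240 counts. Its counts were 0 in the unstranded column of both libraries.

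Among called genes with at least 100 counts in the sum, Mir185, Mir144 and Mir592 followed Mir451a in their ratio towards replicate 2. Mir185, in an intron of Tango2, was 12.4-fold higher in replicate 2, Mir144, the erythroid neighbour of Mir451a, 6.21-fold and Mir592 3.91-fold. Among abundant genes, Mir132 was 1.96-fold higher in replicate 1, Mir139 1.61-fold and Mir21a 3.82-fold, while Mirlet7g was 1.32-fold and Mir126a 1.66-fold higher in replicate 2. By the exact binomial test with Benjamini-Hochberg adjustment, 321 of 546 tested genes differed beyond counting error, 134 higher in replicate 2 and 187 higher in replicate 1. An edgeR exact test at a fixed BCV of 0.1 called 157. Of the 321, 109 differed by 2-fold or more. Among 204 genes at a mean of 100 CPM or more, 179 were called, 26 differed by 2-fold or more and the median fold was 1.29. The test compares those libraries, not conditions, and most calls at high depth are of small folds.

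**Figure D2:**
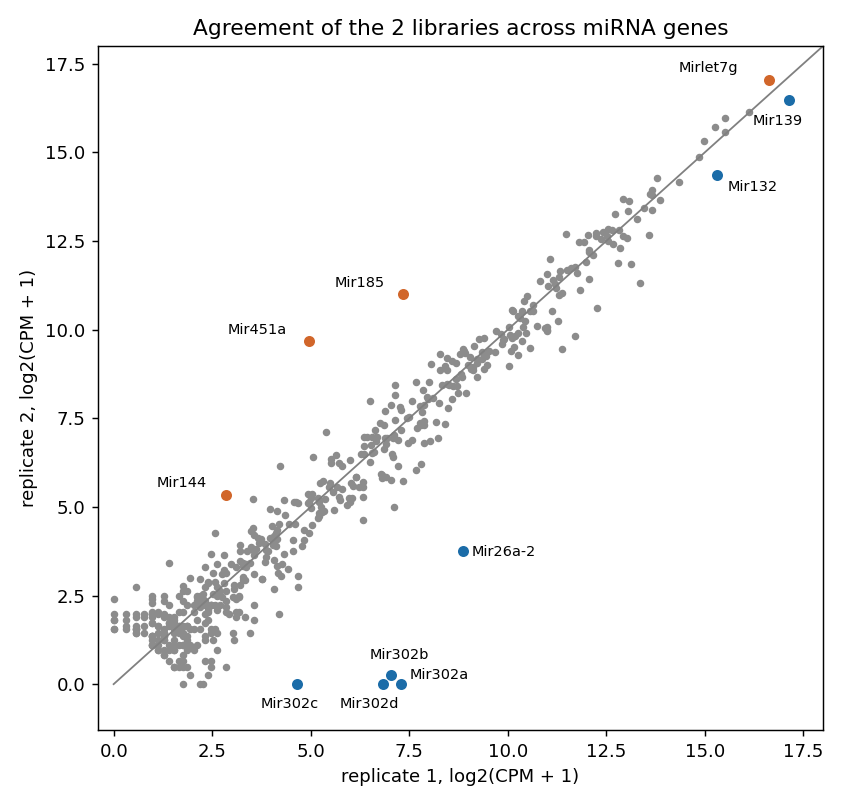
Log2(CPM + 1) of the 546 tested miRNA genes in replicate 1 (horizontal) and replicate 2 (vertical), with the line of equal values. Mir302a to Mir302d and Mir26a-2 lie far below the line, and Mir451a, Mir185 and Mir144 lie far above it.

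Across the tested genes, Pearson's r of log2(CPM + 1) was 0.967 and Spearman's rho was 0.936. Genes are not independent replicates, so no p-value is given. The BCV was 0.481 over tested genes and 0.345 over the 90 genes with 10000 counts or more.

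By their medians, the astrocyte and epithelium lists were lower in replicate 2, and the lists of the choroid plexus and ependyma and of blood were higher. Of the embryonic stem list, only the Mir302 cluster had enough counts to be tested. Of 12 tested astrocyte members, 10 were called higher in replicate 1 and 1, Mir23a, higher in replicate 2, with a median log2 ratio of -0.72 at percentile 0.80 of random lists. The astrocyte share of counts was 4.55% in replicate 1 and 4.15% in replicate 2, and the 3 most abundant members had smaller log2 ratios, -0.21 for Mir23b, -0.34 for Mir29a and 0.50 for Mir23a. All 7 epithelium members were called higher in replicate 1, including Mir200c at 1.89-fold and Mir200b at 4.59-fold, with a median of -1.32 (percentile 0.82). The choroid plexus and ependyma list had a median of 0.46 (percentile 98.06), and 5 of 9 tested members, Mir204, Mir34c, Mir1298, Mir448 and Mir1912, were called, all higher in replicate 2. With at least 100 counts per gene the epithelium median was -1.02 (percentile 4.92) and the choroid median 0.31 (percentile 92.37), both inside the central 95%.

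The blood list had a median of 1.06 (percentile 99.71), but its 4 tested members moved apart. Mir451a and Mir144 were called higher in replicate 2, and Mir486 (1.42-fold) and Mir3107 (5.92-fold) were called higher in replicate 1. Mir486 and Mir3107 lie opposite each other at one locus, and Mir486 shares 10 stretches of 18 bases with its own opposite strand, so their counts are uncertain. The median was 2.64 at 100 counts or more and, in a choice made after seeing the data, 3.69 without these 2 genes, which leaves too few members for a percentile. The 4 tested of 14 embryonic stem members, all from the Mir302 cluster, had a fitted median of -9.53 (percentile 0.01) and a median of -7.86 with zeros set to the floor.

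**Figure D3:**
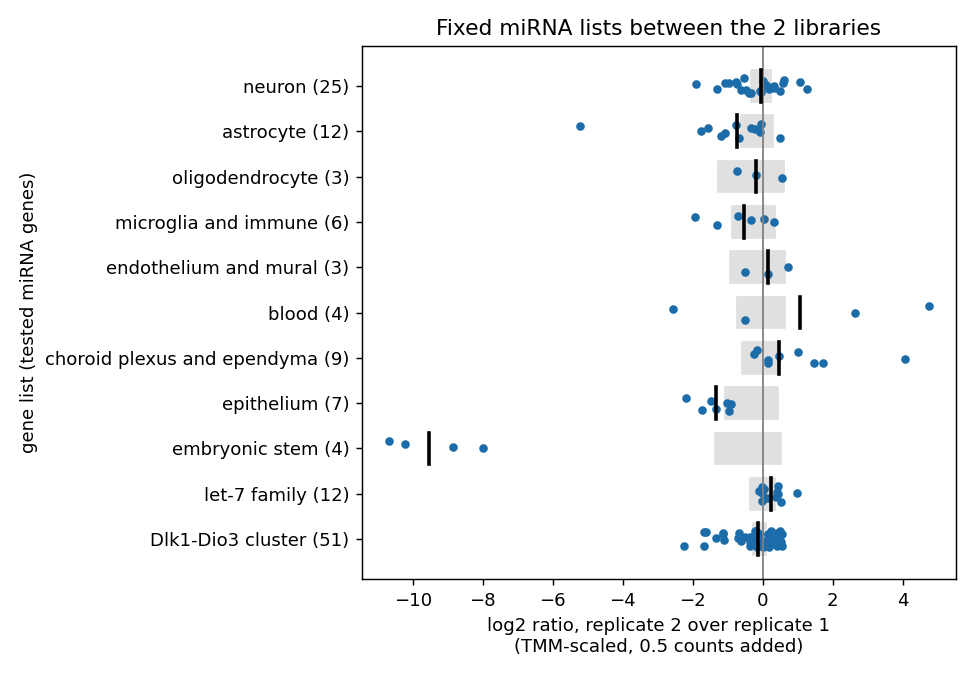
Log2 ratio of replicate 2 over replicate 1 for tested members (points) of 11 gene lists, with list medians (black lines) and the central 95% of medians of random lists matched on expression (grey). The medians of astrocyte, blood, choroid plexus and ependyma, epithelium and embryonic stem lists lie outside the grey range; points of hairpins without counts in a library depend on the 0.5 counts added.

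These 5 lists were the ones outside the central 95% among 19 lists with a value. The random lists treat members as independent, which members of 1 cluster or family are not. The other medians were -0.06 for neuron, -0.20 for oligodendrocyte, -0.53 for microglia and immune, 0.16 for endothelium and mural, -0.74 for muscle and heart, -0.50 for liver, gut and pancreas, 0.41 for posterior Hox, -0.09 for activity-regulated, -0.34 for Alzheimer literature, 0.25 for let-7, 0.24 for miR-30, 0.03 for miR-181, -0.10 for miR-17~92 and -0.13 for Dlk1-Dio3. The meninges and fibroblast list had 1 tested member, Mir214, called higher in replicate 1. Of 13 Alzheimer literature members, 3 were called higher in replicate 2 and 7 higher in replicate 1. Of 25 tested neuron members these numbers were 8 and 12, and of 51 tested Dlk1-Dio3 members 17 and 22. Adjusted over the list alone, 10 let-7 members were called against 8 over all genes tested, and the other lists had equal counts both ways.

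Counts on the opposite strand of miRNA genes made up 6.32% (Wilson 95% interval 6.30 to 6.34) in replicate 1 and 6.59% (6.57 to 6.61) in replicate 2. Of them, 99.94% in each library lay on the 64 genes that overlap a miRNA gene of the other strand, such as Gm25927 opposite Mirlet7e and Mir126b opposite Mir126a. Elsewhere the share was 0.00439% and 0.00419%. In the unstranded column, 13 genes with at least 1000 counts on their own strand in each library kept under 1% of them, Mirlet7e, Mir191, Mir126a and Mir338 among them.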

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

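Of the values not used as the main measure, 4 lay above the limit that a count of 0 allows. That limit is 3 counts, which totals over a library pass in any case. Counts on the opposite strand of miRNA genes numbered 285034 in replicate 1 and 364022 in replicate 2. Of these, 99.94% in each library lay on genes that overlap a miRNA gene of the other strand. Such reads can already be counted in the main measure for the overlapping gene. The 124884 and 154181 opposite-strand counts of Gm25927 equal those of Mirlet7e on its own strand. Elsewhere, opposite-strand counts numbered 173 and 201. Reads mapping to several places numbered 5244644 in replicate 1 and 6290303 in replicate 2, which is 1.24 and 1.22 times the counts on miRNA genes.

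Mir124a and Mir9, which have several loci, had low counts beside single-locus neuronal genes such as Mir132 and Mir137. A candidate explanation is that reads from near-identical loci were set aside as mapping to several places, and another is that these families are less expressed. Within the fixed lists, 20 hairpins that share an 18-base stretch on both sides of the hairpin centre had a median log2(CPM + 1) lower than that of 136 hairpins sharing none, with a difference of -2.42 (bootstrap 95% interval -5.87 to 0.94). Against 63 hairpins that share a stretch on 1 side the difference was -2.98 (-6.63 to 0.70). Both intervals hold 0, so the medians do not tell the explanations apart. They also run over hairpins of all the lists, so they could not decide for Mir124a and Mir9. Every hairpin of Mir124a and Mir9 shares such stretches on both sides, and reads mapping to several places are outside the counts. The low counts of these families therefore do not show low expression. No comparison of groups bears on the explanations, since the design holds 1 group.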

How the results depend on the processing

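The blood median without Mir486 and Mir3107 (3.69) was chosen after the data were seen. Leaving out 1 of 2 libraries moves a mean by less than the SD by construction, so it says nothing about stability of the shares and levels; the share of the 10 most abundant genes was 57.09% to 57.68% when each library set its own top 10. The replicate correlation was 0.975 with no filter on low counts, 0.946 at 100 counts or more, 0.936 as Spearman's rho and 0.943 with a pseudocount of 0.1 CPM. An edgeR exact test at a fixed BCV of 0.1 called 157 genes in place of 321, and the SD of log2 differences at 100 CPM or more gave a BCV of 0.403. Detected genes numbered 472 at 1 CPM, 189 at 100 CPM and 626 at 1 count. With the unstranded column the 10 most abundant genes took 60.2%, and the shares were 4.66% for astrocyte, 0% for oligodendrocyte, 0.629% for endothelium and mural, 0.00247% for blood, 0.00648% for muscle and heart, 1.30% for miR-30, 0.447% for miR-181 and 0.297% for miR-17~92, since hairpins opposite another gene lose their counts there and the total shrinks. The most abundant gene, Mirlet7g, was also taken out of the denominator and, where it was a member, out of the share itself. The top 10 of the remaining genes then took 53.5%, neuron 12.3%, astrocyte 4.93%, muscle and heart 0.00709%, let-7 24.3%, miR-30 1.65%, miR-181 0.472%, miR-17~92 0.314% and Dlk1-Dio3 12.9%. Over all reads, which only enlarges the denominator, the shares were 18.6% for the top 10, 3.52% for neuron, 1.41% for astrocyte, 0.202% for oligodendrocyte, 0.146% for microglia and immune, 0.529% for endothelium and mural, 0.0011% for meninges and fibroblast, 0.0436% for choroid plexus and ependyma, 0.0120% for epithelium, 0.00203% for muscle and heart, 0.0158% for liver, gut and pancreas, 0.00477% for posterior Hox, 1.51% for activity-regulated, 1.69% for Alzheimer literature, 10.8% for let-7, 0.472% for miR-30, 0.135% for miR-181, 0.0899% for miR-17~92 and 3.70% for Dlk1-Dio3. The opposite-strand share was 3.78% without its most abundant gene and 0.00429% without genes opposite another miRNA gene. At 100 counts or more the choroid plexus median was 0.31 and the epithelium median -1.02, both inside the central 95% with fewer members tested. For the 90 named genes, TMM or DESeq2 scaling moved no CPM by more than the SD, the unstranded column moved 19 (and took Mir451a from 426 CPM and Mir3107 from 10.1 CPM to 0, within their SDs), the denominator without the top gene 23 and that of all reads 67. DESeq2 size factors shifted all log2 ratios by 0.06 and changed the sign for Mir330, Mir383, Mirlet7b and Mirlet7e and for the neuron median; total counts shifted them by 0.03 and changed Mirlet7b and Mirlet7e. The causes of other shifts were not tested. No paired analysis was possible because the design holds 1 group.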

Other observations

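The tests of neighbouring hairpins, of hairpins sharing 18 bases, of blood over all differing genes, in Mir486 and without Mir486 and Mir3107, and of explanations for the Mir302 difference were chosen only after the results were seen, as were the genes outside the naming rule (Mir99b, Mir487b, Mir668, Mir448, Mir1912, Mirlet7a-1, Mirlet7c-2, Mirlet7f-1, Mir367 and Mir290 to Mir295). The pair tests at 1000 counts or more were also added then, and the test of hairpins sharing 14 to 17 bases was added after that of 18 bases but set before its own result. Neighbouring hairpins did not always move together between the libraries. Mir99b, Mirlet7e and Mir125a lie within Spaca6 on chromosome 17 between 17830188 and 17830879. Mir99b was 2.27-fold higher in replicate 2 and Mir125a 1.92-fold higher in replicate 1, while the log2 ratio of Mirlet7e was -0.02 and changed sign with DESeq2 size factors and with total counts. In the Dlk1-Dio3 cluster, Mir770 was 1.44-fold and Mir127 1.25-fold higher in replicate 2, while Mir487b was 3.18-fold and Mir668 2.17-fold higher in replicate 1.

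Many miRNA genes differed between the libraries, and blood may account for Mir451a and Mir144, which stays open: the blood list met the planned criterion (median 1.06), yet without Mir486 (-0.51) and Mir3107, whose counts are uncertain, the median of 3.69 rests on Mir451a and Mir144 themselves. The 187 genes higher in replicate 1 do not decide on blood, since scaling centres the ratios. The 54.2% of called genes with 1000 counts or more do not decide on low counts. Of all 546 tested genes, 199 have as many, a share already above the bound set beforehand. Among 204 genes at a mean of 100 CPM or more, however, 179 were called, and the median fold of the 204 was 1.29. Those genes were chosen for high counts, so the calls show only that differences were not confined to genes with low counts. They do not decide on low counts for the other called genes. For GC content, Spearman's rho across genes with the log2 ratio was -0.0791 (bootstrap 95% interval -0.163 to 0.00984) and -0.164 (-0.295 to -0.0192) at 1000 counts or more, under the 0.3 set beforehand but not clearly under 0.1, so a weak trend stays open. Capture that depends on the RNA sequence may contribute: distant hairpins sharing 18 bases differed by a median of 0.47 in log2 ratio (percentile 0.22 of random pairs), although such hairpins can also exchange reads, and those sharing only 14 to 17 bases differed by 0.51 (percentile 1.54, but 7.83 at 1000 counts or more). At 1000 counts or more, most pairs sharing 18 bases were members of the let-7 or miR-30 families. Agreement within a family therefore cannot be told apart from capture. Hairpins recur among the pairs, with 63 pairs from 92 hairpins sharing 18 bases and 400 neighbouring pairs from 163. The pairs are thus not independent, and their percentiles are descriptions only. Neighbours within 10 kb differed by 0.61 (percentile 16.20, and 86.43 at 1000 counts or more). Most neighbouring pairs at 1000 counts or more lie in the Dlk1-Dio3 cluster, so that value largely describes a single locus. Neighbours were thus no more alike than the central 95% of random pairs. The bound set against shared transcription required neighbours to differ more than nearly all random pairs, so the test could hardly decide against it. A difference between animals was not tested. Each tissue sample has 1 library, and the labels do not say that the animals were separate.

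Mir302a to Mir302d were counted in replicate 1 and hardly in replicate 2. Reads from mouse embryonic stem cells are argued against, because Mir290 to Mir295, abundant in those cells, had 0.224% of the counts of the cluster in replicate 1 (4 counts). Capture that favours the AAGTGCT stretch of these hairpins is argued against too, since 11 other tested hairpins holding it had a median log2 ratio of -0.0228 (range -1.54 to 0.41). Another source that holds the Mir302 cluster, such as carry-over between multiplexed libraries, may be the cause, but Mir367 of the same cluster had 0 counts in replicate 1 and may be captured poorly, so this cannot be told apart from a difference of the tissue. No biological explanation of this difference was tested, since each tissue sample has 1 library and tissue cannot be separated from library preparation.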
